A study of Danio rerio with 4 samples.

How the data were processed

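RNA was extracted from livers of adult female zebrafish (Danio rerio, wild-type AB) with the RNeasy Mini Kit, made into libraries with the TruSeq RNA kit and sequenced on an Illumina instrument, per the labels' protocols. Each of the 4 groups (solvent control and 0.02, 0.1 and 0.5 µg/L of the pollutant mixture) was 1 library from a pool of 6 livers, drawn from 3 tanks with 15 females each per concentration and sampled at 84 days. A companion survey of gut bacteria by 16S sequencing was not analysed here.

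The authors deposited 1 table of FPKM (fragments per kilobase of transcript, scaled to the mapped fragments) with 2 decimals, per the file headers. FastQC 0.11.9, cutadapt 2.8, STAR 2.7.1a, RSEM 1.3.3, featureCounts 2.0.0, HTSeq 0.11.2, Cufflinks 2.2.1, DESeq2 1.26.0 and edgeR 3.2.1 are named, with no role or order, per the submitters' processing notes. Which of them made the FPKM, the genome build, the annotation release and whether any of them scaled the values between libraries are not given in the sources used here. The table held no counts, so sequencing depth is unknown and no counting interval or detection floor is given. Among genes with low values in both of 2 libraries, the commonest ratios to control were 1, 0.5, 2 and similar ratios of small decimals, none held by more than 4.10% of those genes, so that no step of single reads could be read from the values and no count test was run. The FPKM sums ranged from 2060157 to 92640146, far from equal. Short RNAs held 47.9%, 26.9%, 58.3% and 69.7% of the sum in control and at 0.02, 0.1 and 0.5 µg/L, and FPKM of very short transcripts can be inflated by the length correction. The number of genes at 1 FPKM or more was 9154, 11505, 8173 and 8758.

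The columns for the exposed libraries are headed 0.002, 0.01 and 0.05, 10-fold below the sample titles. Each heading was matched to the title with the same digit, and the concentration of the titles was used. If the headings are right, every concentration given here is 10-fold too high, while the order of the libraries stays as given.

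The table has 32189 entries, of which 38 hold a dash in place of a value, the 13 protein genes of the mitochondrial genome among them, and were left out, so the mitochondrial genome list has 0 measured genes. Of the remaining 32151 genes, the 10826 with a mean of at least 1 FPKM over the 4 libraries were kept, 76 of them short RNAs. Log2 folds are differences of log2(FPKM + 0.5), a scale that understates changes of low genes. With 1 library per group there is no test and no residual error: genes were called higher or lower at a log2 difference of at least 1 either way. Comparisons were each concentration against control, the 3 pairs of exposed libraries, the same direction at all 3 concentrations, and the order by concentration with at least 2-fold between 0.5 µg/L and control. A gene at 0 in a library may be a failed estimate, and no fold is given for it; 402, 39 and 46 genes were listed at 0 in control and at 5 FPKM or more at 0.02, 0.1 and 0.5 µg/L, and 34, 31 and 44 the other way round. The control library listed 5 genes at 0 that had at least 20 FPKM in every other library. Such genes stay in the counts and list medians, at the value the pseudocount gives.

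Gene lists (36, for pathways of liver and exposure and for markers of other cell types) were written before the values were examined. They were matched to gene names in the table and, for 51 genes, through gene IDs: 1396 list genes were found, 994 were measured and 77 symbols were not found. Of the table's IDs 26350 were in the name table used. Some genes stand in 2 lists, so lists are not independent. For each list the median log2 fold is given with a binomial 95% interval from the ordered values of its genes, which describes the spread between genes and not between pools, and with its percentile among 10000 random lists of the same size matched on mean expression. The genes named in the text were set by a rule fixed before the data were examined: the 10 largest rises and falls at each concentration and over all 3 concentrations among genes above 0 in both libraries, with at least 5 FPKM in the higher library and a symbol that is not a clone or locus name, up to 4 members of each list with the largest mean absolute log2 fold, and a fixed set of liver, insulin and stress genes. Values are given for only some of the genes that the rule names. Genes outside this rule are said to have been chosen after their values were seen. Names such as HPX (1 of many) and members of multigene families can share reads with their copies, and strand use in the authors' counting is not given in the sources used here. Genomic positions are not given, since no build is stated.

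For results that share the control library, 100 sets of unchanged groups were simulated, each library being the control values plus noise drawn from the log2 differences between 0.1 and 0.5 µg/L at similar expression, divided by the square root of 2. All libraries, that at 0.02 µg/L included, thus had the same spread and no offset. Any difference in effect between 0.1 and 0.5 µg/L enters this noise. An ovary-linked share of the 0.02 µg/L library was estimated at 0.1 and 0.5 µg/L as the median over the 22 measured ovary markers of the rise over control divided by the rise at 0.02 µg/L. It was 1.43% and 0.995%. Alternatives set before the data were examined were pseudocounts of 0.1 and 1, no filter or a mean of at least 5 FPKM, median-of-ratios scaling (factors 2.25, 0.830 and 0.951 for 0.02, 0.1 and 0.5 µg/L), trimmed-mean scaling for the counts of genes (2.30, 0.843 and 0.954), and size rules of 1.5-fold and 3-fold. Added after seeing the data were results without the 0.02 µg/L library, the filter mean taken without it, subtraction of the ovary-linked share, and the 0.02 µg/L library scaled to control on hepatocyte markers (factor 0.306).

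The calling of genes over all 3 concentrations was tested on simulated data of 10826 genes with 200 changed 4-fold: 100% were recovered with 0 false calls at a noise SD of 0.1 on the log2 scale, and 98% with 2 false calls at an SD of 0.3. These SDs lie below the spread between the libraries here (SD of the log2 differences 1.18 to 2.51 over the pairs of libraries), so they test the calling procedure and not its error rate in these data. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.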

Results

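Liver RNA was sequenced from adult female zebrafish of the wild-type AB strain after 84 days in flowing water with a mixture of chlorinated persistent organic pollutants. The mixture held 5 organochlorine pesticides and Aroclor1254, a commercial blend of polychlorinated biphenyls, at 0.02, 0.1 or 0.5 µg/L, and control fish received the solvent DMSO. The study asked how such exposure relates to gut microbiota and to effects resembling type 2 diabetes, and the liver libraries bear on the hepatic side of that question. Each of the 4 groups was 1 library made from 1 pool of 6 livers. No value below therefore has a replicate error, no p-value is given, and every difference is a difference between 2 pools. Differences were called by size alone, at 2-fold or more. The deposited values were FPKM without read counts, so sequencing depth was unknown. They summed to 2060157 in control, 92640146 at 0.02 µg/L, 3047757 at 0.1 µg/L and 18280690 at 0.5 µg/L, and the 20 highest entries held 67.9%, 99.1%, 79.6% and 97.2% of these sums. The column headings of the deposited table read 0.002, 0.01 and 0.05, each 10-fold below the sample titles, and were matched to the titles by their digit. Concentrations below follow the titles.

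The liver pool at 0.02 µg/L held egg genes at levels far above the other 3 pools, together with lower levels of liver genes. The egg coat gene zp2.2 stood at 4196 FPKM against 1.38 in control, the oocyte claudin cldnd at 4103 against 0.82, and the maternal gene zar1 at 1108 against 0.76. The mitotic cyclin ccnb1 stood at 1092 against 0.19. All 22 measured ovary and oocyte markers were at least 2-fold higher, with a median log2 fold of 7.00 (95% interval over genes 5.35 to 9.49). Of 22 hepatocyte markers 19 were at least 2-fold lower and none higher, with a median of -1.71 (-2.43 to -1.31). Among them fabp10a, the liver fatty acid binding protein, stood at 5464 FPKM against 25761, and the protease inhibitor gene serpina1 at 385 against 2402. The C-reactive protein family member crp2 was listed at 4156220 FPKM against 105 in control, more than any other named gene. The yolk precursor gene vtg1 was listed at 29063 FPKM at 0.02 µg/L and at 0 in the other 3 libraries, so no fold was formed. Egg coat, vitellogenin and C-reactive protein genes belong to families of near-identical copies, and their single values are uncertain. Over all 10826 measured genes, 5700 were at least 2-fold higher than in control and 1650 lower, with a median log2 fold of 1.12. That split, 77.6% higher, depended on scaling: with median-of-ratios scaling 3521 were higher and 3041 lower, or 53.7% higher. Scaled to control on hepatocyte markers, a choice made after seeing the data, 8521 were higher and 499 lower.

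Cell cycle genes followed the oocyte genes at 0.02 µg/L, with 49 of 54 at least 2-fold higher and a median log2 fold of 5.54. The list of oestrogen response and vitellogenesis genes, which holds the egg coat genes, had 16 of 27 higher, with a median 4.88 above that of all genes. The oestrogen receptor gene esr1 itself was lower, at 12.3 FPKM against 35.6. Endoplasmic reticulum stress genes were higher in 26 of 44, where 52.7% of all genes were higher. Their median lay 0.38 above that of all genes and above 82.14% of random lists. Among the higher members were the chaperone gene hspa5 at 543 FPKM against 24.3 and the disulfide isomerase gene pdia4 at 454 against 5.75. The stress transcription factor gene ddit3 stood lower, at 0.25 against 5.94. Heat shock protein genes (12 of 23 higher, median 1.05) and nuclear-encoded respiratory chain genes (36 of 79 higher, median 0.84) lay near or below the median of all genes, by -0.08 and -0.28, and turned negative with median-of-ratios scaling. Cytosolic ribosomal protein genes were lower in 41 of 77 and higher in none (median -1.09).

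Liver functions stood lower at 0.02 µg/L by most fixed lists. Acute phase, complement and coagulation genes were lower in 61 of 75 (median -1.81). Conjugation and transport genes of xenobiotic phases II and III were lower in 25 of 37 (median -1.65), including the glucuronosyltransferase gene ugt1ab, at 4.11 FPKM against 69.6. Aryl hydrocarbon receptor targets and phase I genes were lower in 20 of 32 (median -1.64). The receptor's usual reporter gene cyp1a stood at 14.1 FPKM against 59.09. Apolipoprotein genes were lower in 17 of 27 (median -1.52), lipogenesis and lipid storage genes in 27 of 52 (median -1.21), and bile acid genes in 16 of 29 (median -1.06). The bile acid enzyme gene cyp7a1 stood at 4.69 FPKM against 24.3. Insulin and glucagon signalling genes went both ways (8 higher and 13 lower of 37, median -0.73), as did glycolysis, gluconeogenesis and glycogen genes (13 higher and 12 lower of 45). The median of the latter was 0.37 as deposited and -0.76 with median-of-ratios scaling. Inflammation genes were lower in 26 of 44 and higher in none (median -1.23, and -0.58 without the filter on low values), and the thyroid hormone list had 2 higher and 5 lower of 10 (median -1.37). NRF2 and antioxidant genes (8 higher and 13 lower of 36, median -0.39), fatty acid oxidation genes (6 and 14 of 46, median -0.30) and cholesterol synthesis genes (8 and 9 of 28, median -0.16) lay closer to control as deposited. All of these stood beside the higher ovary markers and the lower hepatocyte markers of the same pool.

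**Figure D1:**
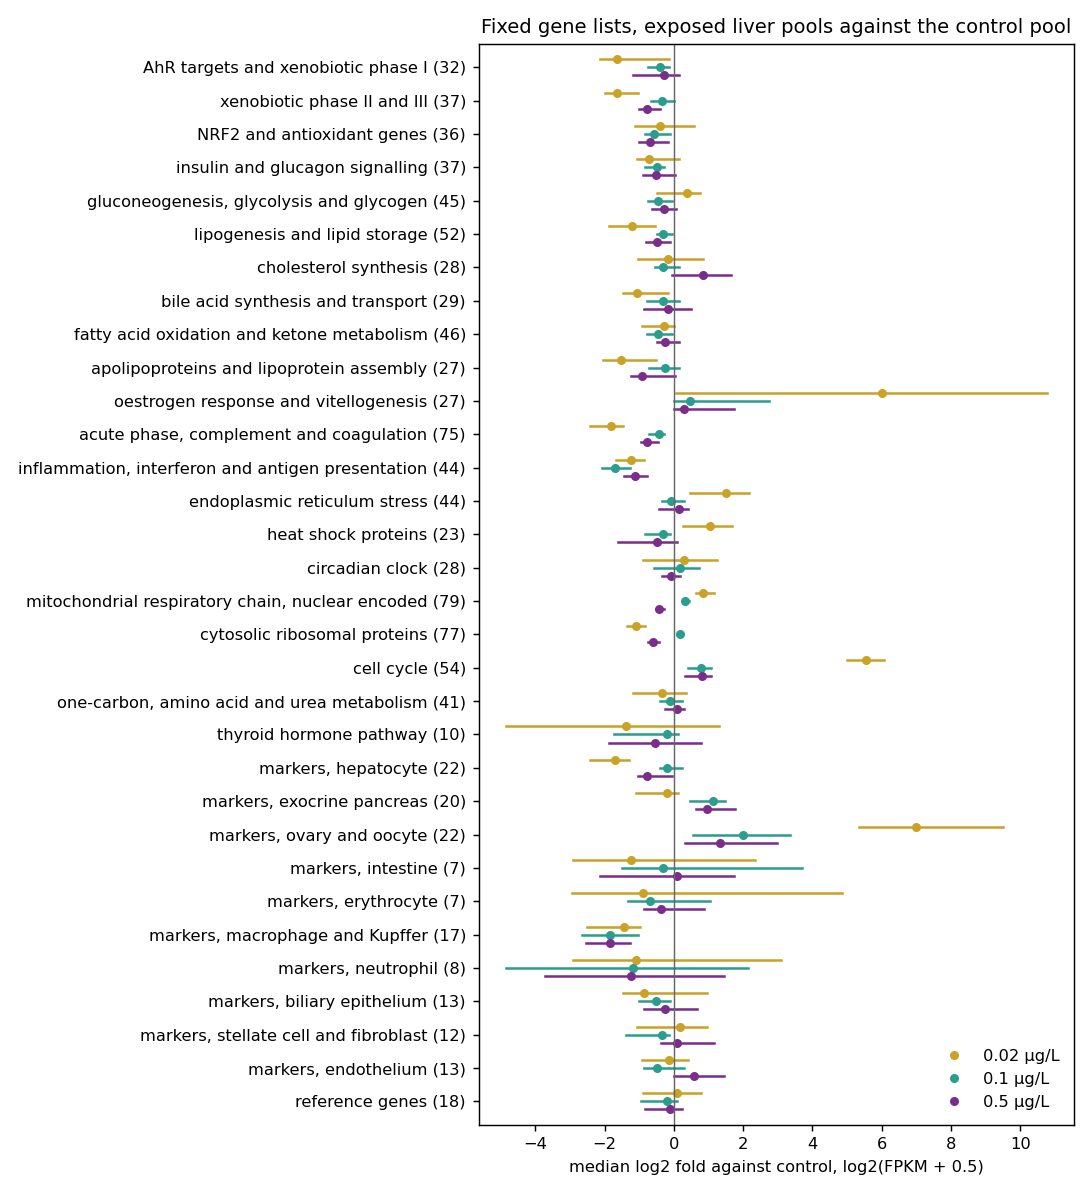
Median log2 fold (horizontal axis, log2 of FPKM plus 0.5) of each fixed gene list with at least 7 measured genes in the pools at 0.02, 0.1 and 0.5 µg/L against the control pool, with the number of measured genes in parentheses. Lines are 95% binomial intervals of the median over the genes of a list, not over pools. Ovary markers (median 7.00) and cell cycle genes (5.54) lie far to the right at 0.02 µg/L, where heat shock and respiratory chain genes change sign with median-of-ratios scaling. Macrophage markers lie left of 0 in all 3 pools.

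At 0.1 µg/L immune genes were lower than in control, and egg and pancreas genes were higher. Of 44 measured genes of inflammation, interferon and antigen presentation 33 were at least 2-fold lower and 1 higher, with a median log2 fold of -1.69 (-2.08 to -1.27), below all 10000 random lists of matched expression. The chemokine gene ccl34a.4 stood at 0.51 FPKM against 36.0 in control, irak3, a brake on Toll-like receptor signalling, at 0.52 against 9.06, and the interferon-induced gene mxc at 0.32 against 9.41. Macrophage and Kupffer cell markers were lower in 13 of 17 (median -1.85), with the granulin gene grn1 at 1.48 against 29.9 and mfap4 at 0.34 against 7.26. Ovary markers were higher in 14 of 22 (median 1.98), with cldnd at 58.5 against 0.82. Cell cycle genes were higher in 22 of 54 (median 0.77). With the filter mean taken without the 0.02 µg/L library, a choice made after seeing the data, these medians were 3.65 and 1.61. Exocrine pancreas markers were higher in 10 of 20 and lower in none (median 1.12, above all random lists), with the chymotrypsinogen gene ctrb1 at 68.2 FPKM against 21.3 and the elastase gene ela2 at 12.7 against 2.04. The tachykinin precursor gene tac4 had the largest rise among ranked genes, from 0.63 to 210 FPKM, with 1.22 at 0.02 µg/L. In total 732 genes were at least 2-fold higher and 1392 lower, and the median of all genes was -0.16. Of the higher genes 252 (34.4%) were among the 331 that stood at least 64-fold above control at 0.02 µg/L. With median-of-ratios scaling the split was 1059 higher and 964 lower, so the higher share went from 34.5% to 52.3%. With a share of the 0.02 µg/L library set from the ovary markers (1.43%) subtracted, an alternative chosen after seeing the data, it was 515 and 1668, or 23.6% higher, and the cell cycle median was -0.034. Without the filter on low values the inflammation median was -0.61.

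Metabolic and detoxification lists moved less at 0.1 µg/L. Insulin and glucagon signalling genes had 1 higher and 9 lower of 37 (median -0.50), with igf1, the growth factor gene of the liver, at 6.74 FPKM against 19.7. Glycolysis, gluconeogenesis and glycogen genes had 2 higher and 8 lower of 45 (median -0.45), with ugp2a, which makes the glycogen precursor UDP-glucose, at 2.63 against 22.1. The gluconeogenic gene pck1 stood at 1113 against 606 and g6pca.1 at 75.8 against 50.6, neither 2-fold apart. Lipogenesis and lipid storage genes had 5 higher and 12 lower of 52 (median -0.32). The lipid droplet gene plin2 stood at 1.55 against 13.2 and the fatty acid synthase gene fasn at 4.99 against 2.01. NRF2 and antioxidant genes were lower in 10 of 36 and higher in 2 (median -0.57), with thioredoxin, txn, at 70.11 against 326 and haem oxygenase, hmox1a, at 5.59 against 26.1. The peroxidase gene gpx3 stood higher, at 22.8 against 5.64. Phase I genes had 2 higher and 8 lower of 32 (median -0.39), with cyp1a at 48.8 against 59.09, and phase II and III genes 3 higher and 8 lower of 37 (median -0.35). Hepatocyte markers lay near control (3 of 22 lower, median -0.19, and 0.08 with median-of-ratios scaling).

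At 0.5 µg/L genes of cholesterol synthesis were higher than in control, while immune genes and several liver lists were lower. Of 28 cholesterol genes 12 were at least 2-fold higher and 2 lower, with a median log2 fold of 0.83 (-0.04 to 1.66) that exceeded 99.99% of random lists. The gene of the rate-limiting enzyme, hmgcra, stood at 21.7 FPKM against 4.75, and the mevalonate pathway gene mvda at 27.7 against 3.76. Among members chosen after their values were seen, hmgcs1 stood at 65.9 against 10.3 and sqlea at 27.5 against 3.10. The sterol esterification gene soat1 was lower, at 0.25 against 6.04. Inflammation genes were lower in 23 of 44 and higher in none (median -1.12, -1.44 to -0.78, and -0.51 without the filter on low values), and macrophage markers were lower in 13 of 17 and higher in 1 (median -1.86). The higher marker was the scavenger receptor gene marco, chosen after its values were seen, at 12.95 FPKM against 2.00. Acute phase, complement and coagulation genes were lower in 24 of 75 and higher in 4 (median -0.77), with the intelectin gene itln3 at 72.8 FPKM against 1347. Exocrine pancreas markers were again higher in 10 of 20 (median 0.96), with ctrb1 at 85.1 against 21.3. Ovary markers were higher in 13 of 22 (median 1.32) and cell cycle genes in 23 of 54 (median 0.80), medians that became 3.05 and 1.28 with the filter mean taken without the 0.02 µg/L library. In total 1433 genes were at least 2-fold higher and 1592 lower, with a median of -0.02 over all genes, and with median-of-ratios scaling 1561 were higher and 1460 lower. Of the 1433 genes 248 (17.3%) were among the 331 that stood at least 64-fold above control at 0.02 µg/L.

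Genes of glucose, lipid and bile acid handling were among those that differed at 0.5 µg/L. The gene igf1 stood at 1.76 FPKM against 19.7, the insulin receptor substrate gene irs2a at 0.36 against 3.25, and igfbp1a, an insulin-repressed binding protein gene, at 132 against 290. Over the 37 insulin and glucagon signalling genes 1 was higher and 8 lower (median -0.51). The glucose output genes pck1 and g6pca.1 were lower, at 209 against 606 and at 21.5 against 50.6. Their list had 3 higher and 9 lower of 45 (median -0.28, -0.63 to 0.05). Lipogenesis and storage genes had 4 higher and 14 lower of 52 (median -0.49), with plin2 at 0.27 against 13.2 and the triglyceride synthesis gene dgat2 at 0.18 against 6.22. The gene fasn stood at 2.28 against 2.01. Apolipoprotein genes had 4 higher and 10 lower of 27 (median -0.91), although apoa1a stood at 4336 against 703. The bile acid enzyme gene cyp7a1 stood at 5.65 against 24.3, in a list with 3 higher and 7 lower of 29 (median -0.18). Fatty acid oxidation and ketone genes had 2 higher and 8 lower of 46 (median -0.25). Hepatocyte markers were lower in 6 of 22 (median -0.77), and fabp10a stood at 14683 against 25761. The genes gck, insrb, irs2b, srebf1 and pparab had means under 1 FPKM over the 4 libraries and were not compared, and the insulin receptor gene insra stood at 4.19 in control and 4.98 at 0.5 µg/L.

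Detoxification lists held more genes lower than higher at 0.5 µg/L, in a pool whose hepatocyte markers had a median of -0.77. Phase II and III genes had 2 higher and 13 lower of 37 (median -0.76), with ugt1ab at 18.6 FPKM against 69.6. NRF2 and antioxidant genes had 2 higher and 12 lower of 36 (median -0.69), with hmox1a at 5.94 against 26.1. Phase I genes went both ways (4 higher and 10 lower of 32, median -0.28). The gene cyp1a stood at 25.6 against 59.09 and the pregnane X receptor gene nr1i2 at 0.08 against 3.86, while cyp2aa4 stood higher, at 7.18 against 0.92. Cytosolic ribosomal protein genes were lower in 20 of 77 (median -0.61) and respiratory chain genes in 13 of 79 (median -0.44). The polyamine enzyme gene sat1a.2 stood at 1377 FPKM against 55.3, with 37.7 at 0.1 µg/L and 2.64 at 0.02 µg/L. In the thyroid hormone list, dio2, the gene of an activating deiodinase, stood at 28.3 against 362, and 1 of 10 members was higher and 2 lower (median -0.54).

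**Figure D2:**
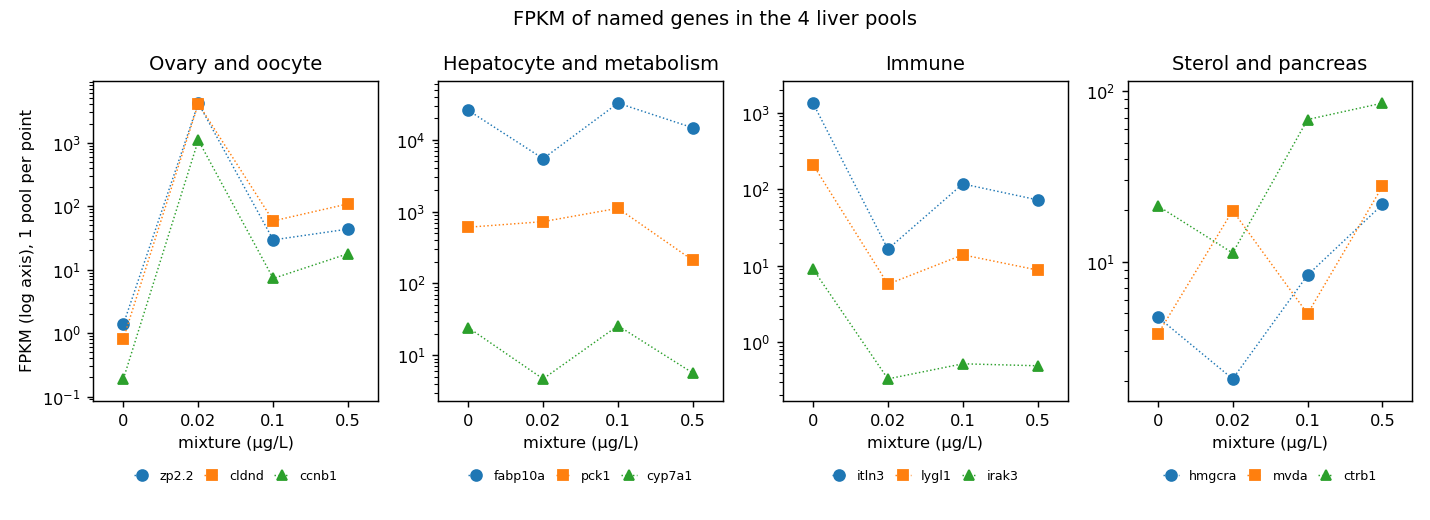
FPKM on log axes of 12 named genes in the 4 liver pools, 1 pool per point, against the concentration of the mixture in µg/L; dotted lines join the points of a gene. The egg coat gene zp2.2 peaks at 0.02 µg/L (4196 FPKM), itln3 is highest in control (1347 FPKM), and hmgcra is highest at 0.5 µg/L (21.7 FPKM).

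Across all 3 concentrations 371 genes were at least 2-fold higher than in control and 412 lower. The highest by their smallest change were egg genes, among them cldnd, zp2.5 (0.98 FPKM in control, 42.2 at 0.1 and 59.7 at 0.5 µg/L) and zar1. Among the lowest, the gene phf20l1 stood at 434 FPKM in control and at 5.23, 9.64 and 1.68 with rising concentration, snap23.2 at 45.8 and at 0.59, 0.52 and 0.49, and steap4 at 166 and at 3.55, 10.0 and 7.76. The lysozyme-like gene lygl1 stood at 211 and at 5.73, 13.9 and 8.77, and itln3 at 1347 and at 16.5, 118 and 72.8. A haemopexin-like gene, HPX (1 of many), stood at 682 and at 6.08, 35.6 and 33.4, and its name marks it as 1 of several copies. All 3 comparisons share the control library. Unchanged groups simulated against it gave medians of 288.5 genes higher and 290 lower, but with the same spread in every library, which leaves out the wider spread and the offset at 0.02 µg/L. Taking each other library as the reference gave 577 and 4896 for 0.02 µg/L, 246 and 67 for 0.1 µg/L and 291 and 221 for 0.5 µg/L. Without the 0.02 µg/L library, a choice made after seeing the data, 454 genes were higher and 666 lower at both 0.1 and 0.5 µg/L, where independent lists would give 96.9 and 204.7 and simulated unchanged groups 475 and 473.5. Some of the excess over independent lists may come from the shared control (simulated ranges 421 to 527 higher and 425 to 534 lower). How much cannot be said from this simulation. At 0.1 µg/L it called a median of 1272 genes higher and 1268 lower, against 732 and 1392 in the data. Its noise also holds any difference in effect between 0.1 and 0.5 µg/L. With the ovary-linked share subtracted, 173 genes were higher at all 3 concentrations, and with the 0.02 µg/L library scaled on hepatocyte markers 230 were lower.

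The log2 folds at 0.1 and 0.5 µg/L correlated across genes with r = 0.58 (0.50 in simulated unchanged groups, range 0.40 to 0.57), and their covariance was 0.96 (0.70 simulated). The simulated r and covariance follow from equal noise in libraries that share a control. That noise was drawn from the differences between 0.1 and 0.5 µg/L, which hold any effect of concentration. The simulated values are therefore no test of a response shared by these pools. With the ovary-linked share subtracted r was 0.50, a value for which no unchanged groups were simulated. Genes are not independent replicates. The folds at 0.02 µg/L correlated with those at 0.1 µg/L with r = 0.51 and with those at 0.5 µg/L with r = 0.47, and their covariances were 1.56 and 1.60 (0.71 and 0.69 simulated). The simulated r of 0.50 for these pairs is no measure of them, since the simulation gave the 0.02 µg/L library the spread of the others.

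**Figure D3:**
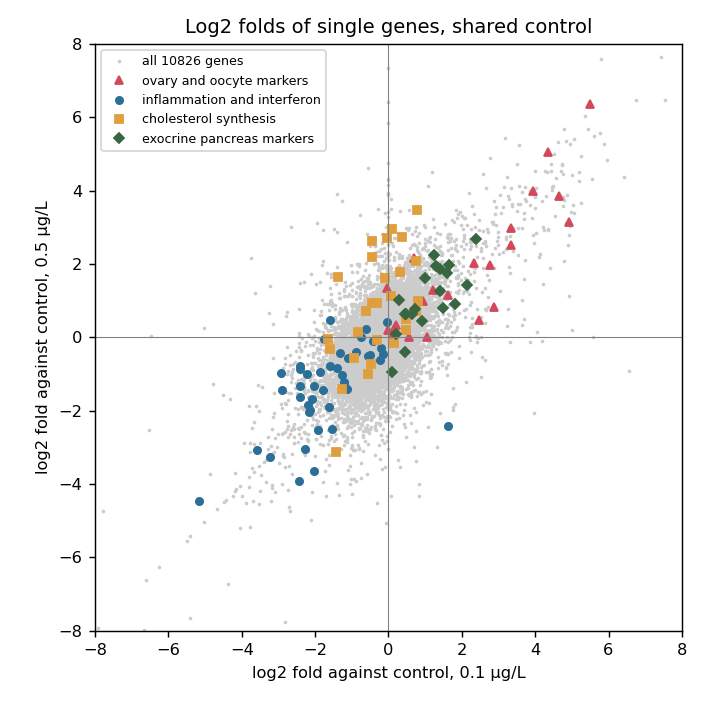
Log2 fold against the control pool at 0.1 µg/L (horizontal) and at 0.5 µg/L (vertical) for 10826 genes, each point 1 gene, on log2 of FPKM plus 0.5; 29 genes lie outside the axes, which end at 8 on either side. Of 22 ovary markers 14 lie at or above 1 on the horizontal axis and 13 on the vertical axis. Of 44 inflammation genes 33 and 23 lie at or below -1 on these axes, and 12 of 28 cholesterol synthesis genes lie at or above 1 on the vertical axis. Both axes share the control.

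Genes that followed the order of the concentrations were counted. Levels rose from control through 0.02, 0.1 and 0.5 µg/L with at least 2-fold between the ends in 115 genes and fell in 169. Simulated unchanged groups gave medians of 268.5 and 268, but without the offset of the 0.02 µg/L library, so the shortfall is no measure of a response to concentration. Among the 12 possible orders of the 4 libraries this one ranked 8. The order control, 0.1, 0.5, 0.02 µg/L held the most genes, 1290 rising and 522 falling. The apolipoprotein gene apoa1a was among the rising genes, at 703, 2363, 2862 and 4336 FPKM. Without the 0.02 µg/L library 922 genes rose and 1099 fell in the order control, 0.1, 0.5 µg/L. No other order of these libraries was counted and no unchanged groups were simulated for it. These counts are therefore no measure of a response to concentration either.

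The exposed pools differed from one another, and the pool at 0.02 µg/L stood apart. Against it 1165 genes were at least 2-fold higher and 6267 lower at 0.1 µg/L, and 1216 higher and 5848 lower at 0.5 µg/L. With median-of-ratios scaling these counts became 2854 and 3516, and 2955 and 3475. The egg gene zp2.2 stood at 4196 FPKM at 0.02 µg/L, 29.4 at 0.1 µg/L and 43.5 at 0.5 µg/L, and the liver gene fabp10a at 5464, 32442 and 14683. Between 0.5 and 0.1 µg/L 1397 genes were higher and 939 lower, and with median-of-ratios scaling 1071 and 1293. In that comparison hmgcra stood at 21.7 against 8.36 FPKM, pck1 at 209 against 1113, cyp7a1 at 5.65 against 25.8, and sat1a.2 at 1377 against 37.7.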

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

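Results without the 0.02 µg/L library, with the filter mean taken without it, with the ovary-linked share subtracted and with hepatocyte scaling were chosen only after the data had been seen; all other settings were set before. No paired analysis was possible because each group is a single library, and no library could be left out within a group. FPKM were already the main values, so the alternative of deposited FPKM in place of counts was not applicable. Without counts, depth could not be used to say which low genes are measured well. Of 150 alternative counts of genes 90 stayed within 1.5 times the main count and 60 moved. Of 635 alternative list medians 43 moved, and 20 changed sign, 3 of them from a main median whose interval excluded 0. Of 2490 values of single named genes 368 moved, and 17 changed sign, 2 of them from a main difference of at least 2-fold. All 17 alternative correlations stayed within 0.1 of the main value, but with the ovary-linked share subtracted r of the folds at 0.1 and 0.5 µg/L was 0.50. Unless the setting itself shows it, the cause of a move was not tested.

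Median-of-ratios scaling applies 1 factor to each library and so moves every gene of a library in the same direction. Because the pseudocount is added afterwards, log2 values of low genes move less. The scaling set the median of all genes to 0.09, 0.03 and 0 in place of 1.12, -0.16 and -0.02 at 0.02, 0.1 and 0.5 µg/L. At 0.02 µg/L against control it gave 3521 genes higher and 3041 lower, and trimmed-mean scaling gave 3476 and 3085. Genes falling with concentration became 102 and, with trimmed-mean scaling, 103. At 0.1 against 0.02 µg/L 2854 were higher and 3516 lower (trimmed-mean 2858 and 3505), and at 0.5 against 0.02 µg/L 2955 and 3475 (trimmed-mean 2990 and 3440). The larger side changed at 0.5 µg/L against control, with 1561 higher and 1460 lower (trimmed-mean 1551 and 1467), at 0.1 µg/L, with 1059 and 964, and at 0.5 against 0.1 µg/L, with 1071 and 1293 (trimmed-mean 1089 and 1265). List medians at 0.02 µg/L became -2.62 for phase I genes, -2.47 for phase II and III, -1.39 for NRF2 genes, -1.43 for insulin and glucagon signalling, -0.76 for glycolysis, gluconeogenesis and glycogen, -1.98 for lipogenesis, -1.13 for cholesterol synthesis, -1.99 for bile acid genes, -1.43 for fatty acid oxidation, -2.50 for apolipoproteins, -2.97 for acute phase genes, -2.23 for inflammation, 0.45 for endoplasmic reticulum stress, -2.26 for ribosomal proteins, 4.40 for the cell cycle and -1.51 for one-carbon metabolism. Of the medians whose interval excluded 0, heat shock genes changed sign to -0.11 and respiratory chain genes to -0.32. Marker medians there became -2.87 for hepatocytes, -1.14 for exocrine pancreas, 1.53 for endocrine pancreas, -1.49 for biliary epithelium and -0.98 for endothelium, and reference genes -1.06. At 0.1 µg/L insulin and glucagon signalling became -0.28, acute phase genes -0.16, respiratory chain genes 0.58 and ribosomal proteins 0.46. The single genes sat2a (-0.14) and alox5b.3 (-0.032) changed sign at 0.02 µg/L.

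A mean of at least 5 FPKM leaves fewer genes. It gave 2992 higher and 901 lower at 0.02 µg/L, 583 lower at 0.1 µg/L, and 918 higher and 738 lower at 0.5 µg/L. It left 186 genes lower at all 3 concentrations, 68 rising and 66 falling with concentration. Between exposed libraries it gave 732 and 3139 for 0.1 against 0.02 µg/L, 721 and 2991 for 0.5 against 0.02 µg/L, and 691 and 518 for 0.5 against 0.1 µg/L. With no filter 685 genes were lower at all 3 concentrations and 289 fell with concentration. The inflammation medians became -0.58, -0.61 and -0.51, and the endocrine pancreas medians became 0, 0.16 and 0.

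The 3-fold rule is stricter by construction. It gave 1030 lower at 0.02 µg/L, 356 higher and 496 lower at 0.1 µg/L, 648 and 682 at 0.5 µg/L, 195 and 164 at all 3 concentrations, and 68 rising and 82 falling with concentration. Between exposed libraries 613 were higher at 0.1 than at 0.02 µg/L, 557 at 0.5 than at 0.02 µg/L, and 456 higher and 348 lower at 0.5 than at 0.1 µg/L. The 1.5-fold rule is looser and gave 1531 higher and 2977 lower at 0.1 µg/L, 2570 and 2926 at 0.5 µg/L, and 784 and 848 at all 3 concentrations. It gave 1864 higher at 0.5 than at 0.02 µg/L, and 2911 higher and 1898 lower at 0.5 than at 0.1 µg/L.

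A pseudocount of 0.1 gave 1150 genes higher at 0.1 µg/L and 647 higher at all 3 concentrations. It set the cell cycle medians to 6.48, 1.37 and 1.12 and the endocrine pancreas median at 0.1 µg/L to 2.56. A pseudocount of 1 set the cell cycle median at 0.02 µg/L to 4.95.

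Without the 0.02 µg/L library 666 genes were lower at both other concentrations, 922 rose and 1099 fell in order, 1 condition fewer by construction. With that library scaled on hepatocyte markers 499 genes were lower there and 230 at all 3 concentrations. With the filter mean taken without it the cell cycle medians were 1.61 and 1.28 and the ovary marker medians 3.65 and 3.05 at 0.1 and 0.5 µg/L. Subtraction of the ovary-linked share left 173 genes higher at all 3 concentrations, set the ovary marker medians at 0.1 and 0.5 µg/L to 0.0064 and 0.0069 by construction, and turned the cell cycle median at 0.1 µg/L to -0.034.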

Other observations

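The tests below were chosen only after the result was seen, except those of a small ovarian share and of dividing cells at 0.1 and 0.5 µg/L and the first test of ovarian RNA on the cholesterol genes. Endothelium markers had 4 higher and 1 lower of 13 at 0.5 µg/L (median log2 fold 0.60, above 99.54% of random lists), against medians of -0.15 at 0.02 and -0.48 at 0.1 µg/L. The receptor gene tek stood at 5.76 FPKM against 1.15 in control and egfl7 at 5.6 against 0.94, while the scavenger receptor gene stab2, a marker of sinusoidal endothelium, stood at 0.20 against 3.24. Stellate cell and fibroblast markers had 4 higher and 2 lower of 12 at 0.5 µg/L (median 0.10, and 0.17 and -0.35 at 0.02 and 0.1 µg/L). The contractile gene acta2 stood at 4.31 FPKM in control and at 37.5, 3.47 and 18.8 at 0.02, 0.1 and 0.5 µg/L, and tagln at 6.64 and at 28.3, 5.22 and 28.8. The RNA malat1, chosen after its values were seen, stood at 1795 FPKM against 226.7, and the creatine synthesis gene gatm, likewise chosen, at 120 and 101 FPKM at 0.1 and 0.5 µg/L against 7.80.

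Values for the other cell types and pathways varied in size and direction. Neutrophil markers were lower in 4, 4 and 5 of 8 and higher in 2, 1 and 2 at 0.02, 0.1 and 0.5 µg/L (medians -1.10, -1.18 and -1.23). The 4 measured lymphocyte markers had medians of -0.60, -0.56 and -1.38, and the 4 of endocrine pancreas 2.46, 1.28 and 0.93, where insb was listed at 0 in control. Biliary markers (13) had medians of -0.86, -0.52 and -0.27, erythrocyte markers (7) of -0.88, -0.70 and -0.38, and intestine markers (7) of -1.25, -0.30 and 0.10. Exocrine pancreas markers had a median of -0.19 at 0.02 µg/L. Circadian clock genes (28) had medians of 0.29, 0.18 and -0.08. The repressor gene nfil3-5 stood at 17.99 FPKM in control and at 0.23, 0.31 and 5.71. One-carbon, amino acid and urea genes (41) had medians of -0.35, -0.12 and 0.08, and reference genes (18) of 0.08, -0.21 and -0.12. Of the pigment cell markers only xdh was measured, at 15.6 FPKM in control and 4.77, 6.06 and 4.92. At 0.1 µg/L respiratory chain genes had a median of 0.32, ribosomal protein genes 0.19, endoplasmic reticulum stress genes -0.08, heat shock genes -0.32, acute phase genes -0.43, apolipoproteins -0.25, bile acid genes -0.32, fatty acid oxidation genes -0.45, cholesterol genes -0.31 and thyroid genes -0.19. Median-of-ratios scaling turns the clock, reference and stellate medians at 0.02 µg/L negative and the stress, one-carbon, thyroid and reference medians at 0.1 µg/L positive.

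Oocyte genes with lower liver genes in the pool at 0.02 µg/L may reflect ovarian tissue collected with the liver: 100% of the 22 ovary markers, none above 1.57 FPKM in control and 1 of them also in the cell cycle list, were at least 2-fold higher, with cldnd at 4103 FPKM. The tables argue against scaling of the FPKM by a few short RNAs, since 1 factor cannot part the ovary and hepatocyte medians by 8.71 on the log2 scale, and against another tissue in place of liver, since the hepatocyte median was -1.71, far above the floor. A response of liver cells to the mixture stays open with 1 pool at 0.02 µg/L. At 0.1 and 0.5 µg/L a small share of ovarian RNA also stays open, because 72.2% and 68.5% of 317 other genes at least 64-fold higher at 0.02 µg/L lay within 2-fold of control plus that share (24.6% and 25.6% without it), short of the 80% set before the test. Dividing liver cells stay open too: after subtraction the cell cycle median was -0.034 (-0.32 to 0.16) at 0.1 µg/L, within the bound set beforehand against them, and 0.34 (-0.27 to 0.67) at 0.5 µg/L, but that bound was wrong because the 0.02 µg/L library is an assumed ovarian profile whose subtraction would remove dividing liver cells as well.

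Immune genes were lower in all 3 exposed pools, with inflammation genes at least 2-fold lower in 26, 33 and 23 of 44 and macrophage markers in 12, 13 and 13 of 17 (median -1.44 at 0.02 µg/L; 1 marker higher at 0.02 and 1 at 0.5 µg/L). Dilution by ovarian RNA lowers immune and liver genes alike and may account for the values at 0.02 µg/L, where the inflammation median lay 0.48 above the hepatocyte median of -1.71, with overlapping intervals. At 0.1 µg/L the tables argue against dilution: the inflammation interval (-2.08 to -1.27) lay below that of the hepatocyte markers (-0.39 to 0.23). The median differences from 0.02 µg/L were -5.11 for ovary markers and 1.57 (1.12 to 1.98) for hepatocyte markers there. That of inflammation genes was only -0.31 (-0.85 to 0.35). At 0.5 µg/L the matching differences, -5.33, 1.16 (0.66 to 1.503) and 0.18 (-0.39 to 0.40), also go against dilution. The inflammation (-1.44 to -0.78) and hepatocyte (-1.03 to -0.05) intervals overlapped at 0.5 µg/L, as at 0.02 µg/L, so that comparison alone cannot decide it. Yet inflammation genes lay about as low at 0.5 as at 0.02 µg/L, while ovary markers differed by -5.33. These values argue against ovarian dilution as the whole cause of the lower inflammation genes at 0.5 µg/L. The tables argue against scaling of the libraries, since the inflammation median at 0.5 µg/L lay -1.10 from that of all genes. Fewer leukocytes alone stay open. The test took acute phase genes made by hepatocytes to stay near control in that case. At 0.5 µg/L 3 of 5 were at least 2-fold lower (hamp, log2 fold -3.53, itln3, -4.20, and leap2, listed at 0), while saa (-0.78) and hp (-0.49) were not. These genes cannot decide it, since hepatocyte markers were lower in the same pool (median -0.77). Whether acute phase genes are independent of leukocytes was not tested. A control pool unusually rich in immune transcripts cannot be told apart from an effect of exposure: the 3 exposed medians lay within 0.57 of one another, and there was 1 control pool.

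Cholesterol synthesis genes were higher at 0.5 µg/L in 12 of 28. The first tests left both technical explanations open: adding the ovary-linked share raised the list median by only 0.0115, and the median lay 0.86 above that of all genes, but its interval (-0.04 to 1.66) reached below the bounds set. In later tests, chosen after that outcome was known, the median exceeded 99.99% of random lists, which argues against scaling since 1 factor moves the random lists alike, and 11 of the 12 genes stayed at least 2-fold higher after subtraction of the share, which decides nothing because it rests on an assumed profile. Ovarian RNA as the whole cause is argued against without that profile: cholesterol genes were higher at 0.5 than at 0.1 µg/L by a median of 1.27 (0.18 to 1.61) while the median difference of the ovary markers was -0.17 (-0.81 to 0.12), and at 0.1 µg/L 0 of 28 cholesterol genes were higher than in control and 5 lower. A chance difference between single pools stays open with 1 pool at 0.5 µg/L, as does a sterol response of the liver to the mixture, which was not tested.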
